A study of Mus musculus with 16 samples.

How the data were processed

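Gene expression was measured by RNA sequencing in 16 mouse cerebral cortex samples in 4 groups of 4, per the labels: Aifm1-KI, a knock-in that deletes arginine 200 of the Aifm1 protein, with littermate wild types (Aifm1-WT), and Hq-mut, the Harlequin mutant, with its own littermate wild types (Hq-WT). Cortices were taken at around postnatal day 180 and received no treatment. The labels describe the Hq stock as B6CBACa Aw-J/A-Aifm1Hq/J but give the strain of every sample as C57BL/6. Each library carries a replicate number from 1 to 4 within its group. The labels speak of mice and littermates but do not state that each library is a separate animal, so the p-values measure the spread between these libraries.

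Per the labels' protocols, total RNA was extracted with TRIzol, checked on a Bioanalyzer and made into libraries with a KAPA mRNA-seq kit, and 51-base single-end reads were produced on an Illumina HiSeq 4000. Per the series' design text, the authors removed adapters and low-quality reads, mapped the rest to the mouse genome mm10 with STAR, obtained counts per gene with htseq-count and tested differential expression with edgeR. The submitters' processing notes give STAR 2.6 and also name SAMtools. The HTSeq version, the annotation release and the strand setting are not given in the sources used here. The deposited values are whole-number read counts per Ensembl gene, not normalized, in 1 table of 16 columns. Counting of uniquely placed reads can lower genes with near-identical copies, and without a stated strand setting reads from a gene and an overlapping antisense gene cannot be told apart.

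The table holds 55573 gene IDs, of which 55394 were paired with a symbol and a position in GENCODE M21 on GRCm38, the assembly that mm10 names, and 16598 have no count in any library. It has 0 rows without a gene ID. Total counts ran from 10671580 in Hq-WT 3 to 32551594 in Aifm1-KI 2, so that a count of 0 allows up to 0.281 and 0.0922 CPM (counts scaled to a common library size), taking 3 counts as the limit. These limits cover counting error only, since reads without molecular identifiers are not independent molecules. CPM were computed over all 16 libraries with TMM factors. Marker levels per library are means of log2 CPM with a prior count of 2. No library was a copy of another: the chi-square statistic per gene between libraries of a group was 3.42 to 96.6 over 24 pairs, and between groups 3.30 to 160 over 96 pairs.

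Each comparison was fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, the default filter on low counts by group, and the quasi-likelihood F-test, and called at a Benjamini-Hochberg adjusted p under 0.05. Aifm1-KI was compared with Aifm1-WT and Hq-mut with Hq-WT in separate fits of 8 libraries. The difference of the mutants' effects was tested over all 16 libraries, and the wild types of the lines were compared with each other. The log2 fold changes are edgeR's, and the standard error (SE) is the fold change divided by the square root of the F statistic. In each line, 33 gene lists with 505 genes were tested with camera from limma 3.58.1 at its preset correlation of 0.01, two-sided and adjusted over the 33 lists, next to camera with an estimated correlation and fry. The difference of effects and the wild types were tested over the lists in the same way. Of the 505 genes, 504 were found in the table. Numbers of list members higher or lower cover only those that passed the filter on low counts in that fit.

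The 19 lists of pathways and gene groups are complex I subunits, complexes II to V subunits, mitochondrially encoded genes, complex I assembly and intermembrane-space import, ATF4 and integrated stress response, mitochondrial chaperones and proteases, antioxidant and NRF2 targets, p53 targets and apoptosis, glycolysis and glucose uptake, TCA cycle, cholesterol synthesis, immediate early genes, synaptic vesicle machinery, interferon-stimulated genes, reactive astrocyte genes, disease-associated microglia genes, X-linked neighbours of Aifm1, genes that differ between mouse strains, and sex-linked genes. The 14 lists of markers are astrocyte, microglia, inhibitory neuron, excitatory neuron, oligodendrocyte, oligodendrocyte precursor, endothelium, pericyte and smooth muscle, blood, meninges, choroid plexus, striatum, hippocampus and thalamus.

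Groups, tests, lists, the first set of alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, for each mutant line, Aifm1; up to 10 called genes in each direction with the largest fold change, a mean log2 CPM of at least 0 and no overlap between mutant and wild-type libraries, leaving out predicted genes and pseudogenes by their symbols; of each list up to 4 called members, or the member with the smallest p where none was called; up to 10 genes called in both lines in the same direction; up to 5 genes per direction for the difference of effects; and the sex-linked genes. Any other gene named was chosen after its values were seen, and the text says so. A list of 20 liver transcripts was also written after the data were seen.

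The replicate numbers were checked for pairing, in a range of 0.1 and above for every pair's correlation. In the Hq line, the deviations of same-numbered Hq-mut and Hq-WT libraries from their group means correlated across genes at r = 0.358 to 0.494, those of differently numbered libraries at -0.359 to 0.085, and 8 of 8 libraries correlated best with their own number. The pairing thus comes from the data, and the labels do not say what a number marks. The tests fixed beforehand for the Hq line and for the difference of effects do not use the pairs, so their values are without pairing unless a block or a pair is named.

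The alternatives tried were RLE and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, all 16 libraries in 1 fit, a minimum fold change of 1.5, and leaving out each library in turn. Alternatives chosen after the data were seen were edgeR's likelihood ratio test, fits without libraries that stood apart in marker levels, the striatal marker level as a covariate, and other tools with the block in the Hq line.

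Counts were simulated from the means and depths of these libraries, with 100 genes changed by 2-fold and 100 by 4-fold. The changed genes all had a mean above 1 CPM. The edgeR procedure was tested for their recovery. It recovered 81 and 96 of them for the Aifm1-KI comparison over 18383 genes, 74 and 99 for the Hq-mut comparison over 17969 genes, 54 and 93 for the difference of effects over 19129 genes, and 83 and 98 for the wild types over 18106 genes. False calls numbered 13, 10, 8 and 12 in the same order, among 207, 193, 157 and 208 calls. DESeq2 made more on the same counts, 35, 38, 24 and 41 among 237, 230, 187 and 243 calls. For the list tests, 30 genes changed by 1.5-fold formed a list, which camera found in the simulations of both lines. Of 20 lists of unchanged genes, 0 had a camera p under 0.05 in each. The simulated genes vary independently of each other, unlike real ones, so this does not test the preset correlation. The simulations also hold no pairs and no libraries that stand apart in marker levels. Recovery in the real data, and for genes at lower levels, may therefore differ. Copies of Gm6166 were sought with blastn 2.17.0 in the GENCODE M21 transcripts. Tables were handled with pandas 2.3.3 in Python 3.11.15 and plots drawn with matplotlib 3.10.9. No column of the table was left out.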

Results

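Transcript levels were measured in cerebral cortex of mice at postnatal day 180 or around it, in a line with a knock-in deletion in Aifm1 and in the Harlequin line, each with littermate wild types. Aifm1 encodes apoptosis-inducing factor, a flavoprotein of the mitochondrial intermembrane space that is needed for respiratory chain assembly, and Harlequin is a mutation of the same gene. Each of the 4 groups (Aifm1-KI, Aifm1-WT, Hq-mut and Hq-WT) held 4 libraries, which the labels give as separate samples. Total counts per library ran from 10671580 in Hq-WT 3 to 32551594 in Aifm1-KI 2. The Y-linked gene Ddx3y had a mean of 72.5 to 75.6 CPM (counts scaled to a common library size) in every group, and Xist, the RNA of the inactive X chromosome, a mean of 0.19 to 0.66 CPM.

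Aifm1 itself (ENSMUSG00000036932, protein-coding, GRCm38 chromosome X 48474944 to 48513563, minus strand) fell in Hq-mut, where it was at 3.32 ± 0.79 CPM (SD, n = 4) against 23.9 ± 1.25 CPM (SD, n = 4) in Hq-WT. The log2 fold change was -2.87 (SE 0.19, edgeR adjusted p = 0.000348), a level 7.32-fold lower, with all 4 mutant libraries below all 4 wild types. With replicate pairs as a block it was -2.89 (edgeR adjusted p = 0.00101). In Aifm1-KI the transcript was at 23.7 ± 1.84 CPM (SD, n = 4) against 22.7 ± 0.81 CPM (SD, n = 4) in Aifm1-WT, a log2 fold change of 0.08 (SE 0.07, edgeR adjusted p = 0.679). Counts per gene do not show the deleted codon, so the knock-in genotype was not checked by them.

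**Figure D1:**
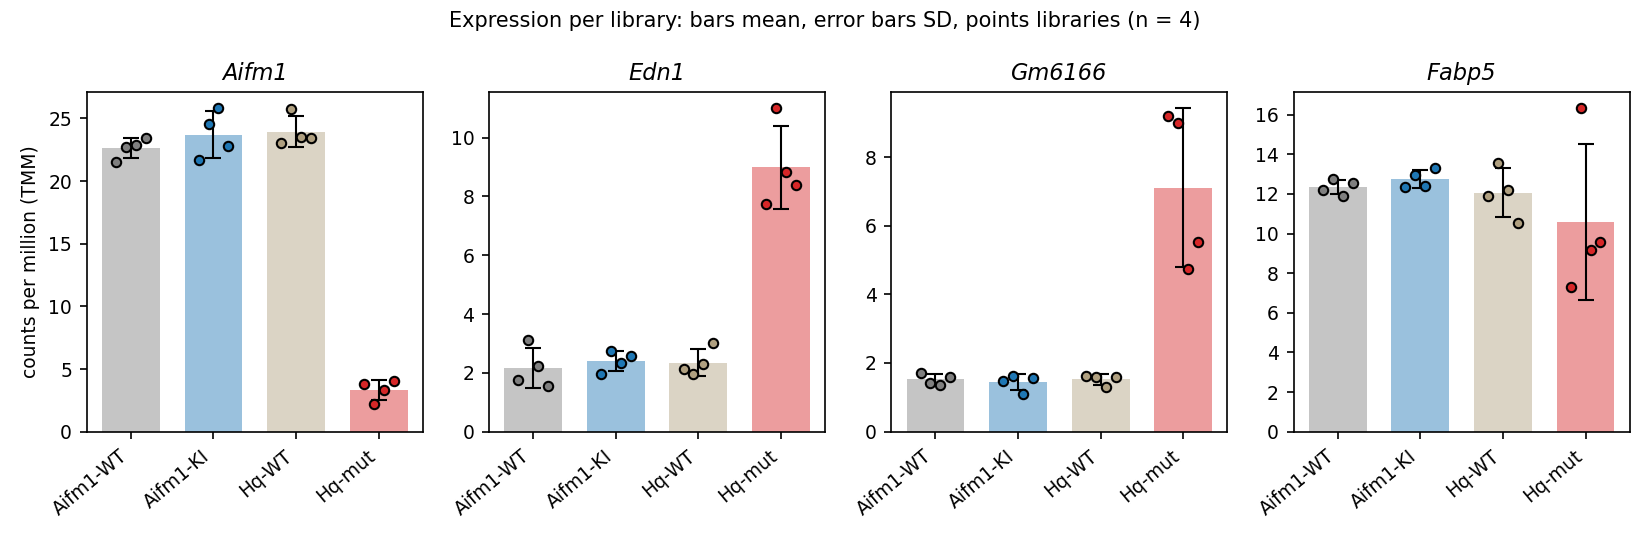
Levels of Aifm1, Edn1, Gm6166 and Fabp5 in CPM for each of the 16 libraries (points) by group, with bars at the group mean and error bars of 1 SD (n = 4). Aifm1 lies at 3.32 CPM on average in Hq-mut and between 22.7 and 23.9 CPM in the other groups, and Edn1 and Gm6166 are higher in Hq-mut than in Hq-WT.

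The comparison of Aifm1-KI with Aifm1-WT asks which cortical transcripts differ in mice with the deletion. No single gene passed the test. Among named genes, the dopamine receptor gene Drd2, a marker of striatal neurons, was at 6.57 ± 5.03 CPM (SD, n = 4) in Aifm1-KI against 0.86 ± 0.06 CPM (SD, n = 4) in Aifm1-WT. That is a log2 fold change of 2.98 (SE 0.62, edgeR adjusted p = 0.368). Slc16a1, a monocarboxylate transporter, had a log2 fold change of -0.40 (SE 0.09), Tdo2, a tryptophan-degrading enzyme used here as a hippocampal marker, -1.96 (SE 0.47), and the thalamic marker Lhx9 2.48 (SE 0.76). The edgeR test called 0 of 18383 genes, with 2094 at an unadjusted p under 0.05 where chance gives 919, and the lowest adjusted p was 0.368. DESeq2 called 82 genes (47 higher, 35 lower), edgeR's likelihood ratio test 110 and limma-voom 0. Of the 82, 6 were striatal markers, all higher, and 16 were among 20 liver transcripts listed after the data were seen, all lower. The 20 liver transcripts summed to 422, 496, 54.2 and 38.8 CPM in Aifm1-WT 1 to 4 and 9.51 to 25.6 CPM in Aifm1-KI. Without Aifm1-KI 3, edgeR called 46 genes (43 higher, 3 lower), among them Drd2 at 3.30 with an adjusted p of 0.0295.

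Among gene lists in Aifm1-KI, markers of the striatum and of oligodendrocyte precursors rose and those of 7 lists fell. All 10 striatal markers were higher, with a median log2 fold change of 1.36 (camera adjusted p = 2.8e-14, adjusted p = 0.414 with an estimated correlation), and adjusted over the list alone 9 were called higher. Of these, Adora2a (2.34, SE 0.53), an adenosine receptor, and Penk (2.05, SE 0.59), the proenkephalin gene, were chosen after their values were seen. The markers were unevenly spread: their mean log2 CPM was 4.01, 5.28, 3.14 and 5.16 in Aifm1-KI 1 to 4 against 2.80 to 3.28 in Aifm1-WT. Without Aifm1-KI 2 and 4, the median was 0.45 (camera adjusted p = 5.9e-08, adjusted p = 0.353 with an estimated correlation), with 9 of the 10 higher.

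Oligodendrocyte genes, which encode myelin proteins, fell in Aifm1-KI, with 10 of 10 lower, a median of -0.41 and Opalin at -0.59 (SE 0.25) (camera adjusted p = 2.7e-05, adjusted p = 0.581 with an estimated correlation). Markers of their precursors rose, 6 of 6, with a median of 0.33 (camera adjusted p = 0.00163, adjusted p = 0.581 with an estimated correlation) and the proteoglycan gene Cspg4 at 0.36 (SE 0.14). Excitatory neuron markers fell, 9 of 10, with a median of -0.27 (camera adjusted p = 0.00464, adjusted p = 0.581 with an estimated correlation), and adjusted over the list alone 1 was called higher and 2 lower. Rorb, a layer marker, was at -0.44 (SE 0.13). All 15 immediate early genes, which respond to neuronal activity, were lower, with a median of -0.43 (camera adjusted p = 0.000288, adjusted p = 0.617 with an estimated correlation), and without Aifm1-WT 4 the adjusted p was 0.0726. The libraries with high striatal markers moved with these groups: without Aifm1-KI 2 and 4, the medians were -0.05 for oligodendrocytes (camera adjusted p = 0.728), 0.01 for precursors (0.728), 0.05 for excitatory neurons (0.728) and -0.10 for immediate early genes (0.54). Aifm1-KI 2 had a mean log2 CPM of 6.43 over excitatory neuron markers, and the other libraries of its line 7.14 to 7.51.

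Interferon-stimulated genes fell in Aifm1-KI, 14 of 17, with a median of -0.29 (camera adjusted p = 0.000706, adjusted p = 0.387 with an estimated correlation) and the antiviral gene Ifit1 at -0.96 (SE 0.25). Endothelial markers fell, 9 of 10, with a median of -0.24 (camera adjusted p = 0.00113, adjusted p = 0.581 with an estimated correlation), 2 of them called lower adjusted over the list alone, and Tek, an angiopoietin receptor, was at -0.48 (SE 0.12). Pericyte and smooth muscle markers fell, 8 of 8, with a median of -0.29 (camera adjusted p = 0.00605, adjusted p = 0.581 with an estimated correlation). This p was 0.117 without Aifm1-KI 3 and 0.0708 without Aifm1-WT 2. Subunits of respiratory complexes II to V fell slightly, 37 of 39, with a median of -0.07 (camera adjusted p = 0.00133, adjusted p = 0.702 with an estimated correlation), and Uqcrc1 of complex III was at -0.14 (SE 0.07). That call was lost without Aifm1-WT 4 (camera adjusted p = 0.0997) and without Aifm1-KI 2 and 4 together (0.0529). Without the same 2 libraries, the medians were -0.22 for interferon-stimulated genes (camera adjusted p = 0.00113), -0.22 for endothelium (0.00193) and -0.30 for pericytes (0.000255). In the same order, these had an adjusted p of 0.267, 0.520 and 0.446 with an estimated correlation. With the striatal marker level as a covariate, endothelium (-0.17, 0.0547) and complexes II to V (-0.03, 0.440) did not pass. Interferon-stimulated genes (-0.20, 0.0102, adjusted p = 0.452 with an estimated correlation) and pericytes (-0.23, 0.00609, adjusted p = 0.541 with an estimated correlation) did.

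The other lists did not pass the test in Aifm1-KI. The respiratory and metabolic ones had medians of -0.04 for complex I subunits (camera adjusted p = 0.0577; 30 of 36 lower, Ndufs6 at -0.19, SE 0.08), 0.04 for mitochondrially encoded genes (0.749), -0.05 for complex I assembly and import (0.477). They were -0.04 for the TCA cycle (0.260), -0.0070 for glycolysis (0.280, with Slc16a1 called lower adjusted over the list alone) and 0.02 for cholesterol synthesis (0.208). Stress lists lay at -0.04 for ATF4 and integrated stress response (0.280), -0.01 for mitochondrial chaperones and proteases (0.923), -0.04 for antioxidant genes (0.173) and -0.11 for p53 targets (0.0731). Glial lists lay at -0.14 for reactive astrocytes (0.0579), -0.08 for disease-associated microglia (0.0734), -0.03 for astrocytes (0.0969, with 1 gene called lower adjusted over the list alone) and -0.05 for microglia (0.0885). Without Aifm1-KI 2 and 4, all 4 glial lists passed as lower, reactive astrocytes at -0.22 (camera adjusted p = 3.0e-06, adjusted p = 0.115 with an estimated correlation) and disease-associated microglia at -0.30 (6.1e-11, adjusted p = 0.0858 with an estimated correlation). Astrocytes were then at -0.19, 12 of 12 lower (4.0e-09, adjusted p = 0.0858 with an estimated correlation), and microglia at -0.22, 16 of 17 lower (9.5e-09, adjusted p = 0.353 with an estimated correlation). Medians were -0.09 for synaptic vesicle machinery (0.0885), 0.06 for inhibitory neurons (0.919), -0.32 for blood (0.083) and -0.07 for meninges (0.384). Other regions had 1.61 for choroid plexus (0.120), 0.27 for hippocampus (0.663, with 1 higher and 1 lower called adjusted over the list alone) and 0.39 for thalamus (0.0773). The choroid plexus median came with Aifm1-KI 2, whose mean log2 CPM over these markers was 4.94 where Aifm1-KI 1, 3 and 4 had 0.20 to 0.62. X-linked neighbours of Aifm1 lay at -0.03 (0.997), genes that differ between strains at 0.29 (0.0885) and sex-linked genes at 0.15 (0.117). Median and mean or test differed in sign for chaperones (median -0.01, mean 0.0042, tested lower), X-linked neighbours (median -0.03, mean 0.0083, tested higher) and inhibitory neurons (median 0.06, mean 0.04, tested lower). In all, 9 of 33 lists passed, 0 with an estimated correlation and 0 by fry, and 16 passed without Aifm1-KI 2, 15 without Aifm1-KI 4 and 15 without Aifm1-WT 3. With no filter on low counts 20 passed, 5 higher and 15 lower, among them the 9 (lowest adjusted p = 0.211 with an estimated correlation), and without Aifm1-KI 2 and 4 together 14 passed.

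The comparison of Hq-mut with Hq-WT asks which transcripts differ in Harlequin cortex. Besides Aifm1, 2 genes rose. Edn1 (GRCm38 chromosome 13 42301476 to 42307990), which encodes the vasoconstrictor peptide endothelin-1, was at 8.99 ± 1.41 CPM (SD, n = 4) against 2.35 ± 0.46 CPM (SD, n = 4), a log2 fold change of 1.91 (SE 0.20, edgeR adjusted p = 0.0179). Gm6166 (GRCm38 chromosome 9 57483963 to 57484371), annotated as a processed pseudogene, was at 7.11 ± 2.31 CPM (SD, n = 4) against 1.53 ± 0.16 CPM (SD, n = 4), a log2 fold change of 2.18 (SE 0.26, edgeR adjusted p = 0.0371). It was named after its values were seen, and its level is uncertain because its sequence is 98.3% identical over 409 bases to that of Fabp5, a fatty acid-binding protein gene, which was at 10.6 ± 3.94 against 12.1 ± 1.24 CPM. Trib3, a pseudokinase gene of the integrated stress response, was at 1.10 ± 0.20 against 0.26 ± 0.22 CPM (edgeR adjusted p = 1). In Hq-WT it lay at 0.054 to 0.46 CPM, around the 0.141 to 0.281 CPM that a count of 0 allows there. Its fold change is therefore uncertain.

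The edgeR test called 3 of 17969 genes in the Hq line, with 385 at an unadjusted p under 0.05 where chance gives 898. This fit leaves what pairs share in its spread between libraries, with a common dispersion of 0.0456, against 0.0144 with the block. With the block edgeR called the same 3 genes, with 1433 unadjusted, Edn1 at an adjusted p of 0.0231 and Gm6166 at 0.0147. DESeq2 with the block called 33 and the likelihood ratio test with the block 54. The fits with a library left out do not use the block and keep the partner of that library. In them Edn1 lost its call without Hq-mut 3 (edgeR adjusted p = 0.0558), Hq-mut 4 (0.059), Hq-WT 1 (0.148), Hq-WT 2 (0.078) or Hq-WT 3 (0.139). Gm6166 lost it without Hq-mut 1 (0.131), Hq-mut 2 (0.0968), Hq-mut 4 (0.059), Hq-WT 1 (0.236), Hq-WT 2 (0.222), Hq-WT 3 (0.281) or Hq-WT 4 (0.257), and with limma-voom (0.171). Aifm1 kept its call in all of these fits, and the counts ran from 1 to 2 with a library left out.

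Among gene lists in Hq-mut, ATF4 and integrated stress response genes rose, 22 of 26, with a median log2 fold change of 0.16 (camera adjusted p = 2.2e-06, adjusted p = 0.460 with an estimated correlation). Trib3, near the limit of a count of 0 in Hq-WT, was called higher adjusted over the list alone. Interferon-stimulated genes rose, 16 of 17, with a median of 0.21 (camera adjusted p = 0.000209, adjusted p = 0.460 with an estimated correlation) and the membrane protein gene Ifitm3 at 0.70 (SE 0.33). Genes of cholesterol synthesis rose, 19 of 20, with a median of 0.15 (camera adjusted p = 0.0005, adjusted p = 0.460 with an estimated correlation) and Fdps, farnesyl diphosphate synthase, at 0.43 (SE 0.23). Without Hq-mut 2 the adjusted p was 0.0557. Synaptic vesicle genes rose, 15 of 17, with a median of 0.11 (camera adjusted p = 0.00441, adjusted p = 0.607 with an estimated correlation). This call was lost without Hq-mut 2 (0.0768) or Hq-WT 3 (0.196). Without the pair of libraries numbered 2, the medians were 0.09 for ATF4 genes (camera adjusted p = 0.031, adjusted p = 0.835 with an estimated correlation), 0.12 for interferon-stimulated genes (0.0638) and 0.08 for cholesterol synthesis (0.0862).

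Subunits of complexes II to V rose in Hq-mut, 37 of 39, with a median of 0.14 and Cox7c of complex IV at -0.32 (SE 0.30) (camera adjusted p = 0.0296, adjusted p = 0.822 with an estimated correlation). With the block 36 of 39 were higher, at 0.10 (camera adjusted p = 0.00207), where 0.609 was the lowest adjusted p of any list with an estimated correlation. The rise rested on pair 2, without which the median was -0.04 (0.647). Without Hq-mut 2 but with its partner Hq-WT 2 kept, the median was -0.19 (9.7e-06, adjusted p = 0.841 with an estimated correlation). The call was also lost without Hq-WT 1 (0.245), Hq-WT 3 (0.489) or Hq-WT 4 (0.344). Mitochondrially encoded genes fell, 6 of the 7 tested, with a median of -0.07 and mt-Nd2 at -0.36 (SE 0.12) (camera adjusted p = 0.0104, adjusted p = 0.693 with an estimated correlation). The other genes of this list were not tested, as they did not pass the filter on low counts. Why their counts were low was not examined, so the 7 do not stand for the whole list. The call was lost without Hq-mut 3 (0.0854), Hq-mut 4 (0.121), Hq-WT 2 (0.103), Hq-WT 3 (0.112) or Hq-WT 4 (0.0615), and without pair 3 (-0.02, 0.272). Glycolysis genes rose, 19 of 24, with a median of 0.11 and Gapdh at -0.47 (SE 0.16) (camera adjusted p = 0.046, adjusted p = 0.775 with an estimated correlation). The glycolysis call did not hold without Hq-mut 1 (0.107), Hq-mut 2 (0.966), Hq-WT 3 (0.212) or Hq-WT 4 (0.294), or without pair 2 (0.337). Gapdh was at 7.11 CPM in Hq-mut against 9.72 in Hq-WT, Cox7c at 2.09 against 2.56 and Fdps at 4.54 against 3.31. Whether near-identical copies lowered these counts was not tested, so their fold changes are uncertain. Complex I subunits, of which 35 of 36 were higher, did not pass (median 0.13, camera adjusted p = 0.0829). With the block they did (median 0.08, camera adjusted p = 0.0139, adjusted p = 0.718 with an estimated correlation), and they were lower without Hq-mut 2 (median -0.24, 6.8e-07, adjusted p = 0.841 with an estimated correlation). That fit keeps Hq-WT 2, and without the whole pair the median was -0.04 (0.351).

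Cell type and region lists also passed in Hq-mut. Striatal markers rose, 9 of 9, with a median of 1.07 and Drd2 at 2.13 (SE 0.71) (camera adjusted p = 9.4e-08, adjusted p = 0.460 with an estimated correlation). Their mean log2 CPM was 3.98, 3.10, 5.68 and 3.43 in Hq-mut 1 to 4 and 2.99 to 3.30 in Hq-WT, and without the pair numbered 3 the median was 0.24 (0.0874). Blood transcripts, most of them for haemoglobin chains, fell, 5 of 5, with a median of -0.54 and Hba-a2 at -0.89 (SE 0.26) (camera adjusted p = 4.1e-05, adjusted p = 0.460 with an estimated correlation), and adjusted over the list alone 1 was called lower. The median was -0.26 without the pair numbered 3 (0.0121, adjusted p = 0.641 with an estimated correlation) and -0.80 without pair 2 (2.6e-06, adjusted p = 0.835 with an estimated correlation). Choroid plexus markers fell, 10 of 10, with a median of -2.46 (camera adjusted p = 0.00361, adjusted p = 0.760 with an estimated correlation). Hq-WT 2 had a mean log2 CPM of 4.93 over them, and without it the median was 0.45 (0.355), and without pair 2 0.04 (0.872). Without Hq-mut 4 the adjusted p was 0.0638. Oligodendrocyte markers rose, 10 of 10, with a median of 0.18 (camera adjusted p = 0.0205, adjusted p = 0.775 with an estimated correlation). This did not hold without Hq-mut 2 (0.429), Hq-mut 3 (0.418), Hq-WT 1 (0.193), Hq-WT 2 (0.632) or Hq-WT 4 (0.097). Without pair 2 the median was -0.09, with 9 of 10 lower (0.803), and without pair 3 it was 0.47 (1.3e-08, adjusted p = 0.641 with an estimated correlation). Pericyte and smooth muscle markers fell, 7 of 8, with a median of -0.18 (camera adjusted p = 0.0454, adjusted p = 0.760 with an estimated correlation). The result was lost without Hq-mut 1 (0.485), Hq-mut 2 (0.218), Hq-WT 3 (0.422) or Hq-WT 4 (0.509), and without pair 3 (0.191), while without pair 2 the median was -0.27 (0.031, adjusted p = 0.835 with an estimated correlation). Immediate early genes fell, 13 of 15, with a median of -0.10 (camera adjusted p = 0.0175, adjusted p = 0.760 with an estimated correlation). This list lost its call without Hq-mut 4 (0.593), Hq-WT 2 (0.258) or Hq-WT 4 (0.423), and without pair 2 (-0.09, 0.143), while without pair 3 its median was -0.16 (1.6e-06, adjusted p = 0.641 with an estimated correlation).

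**Figure D2:**
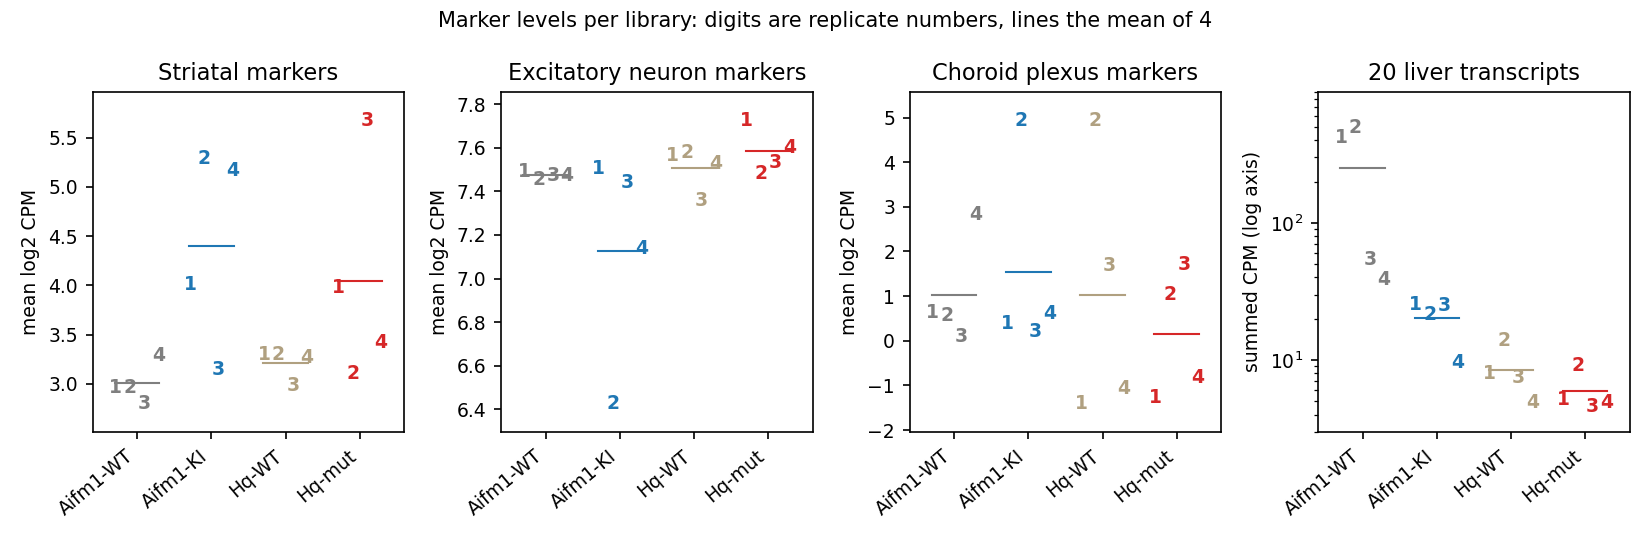
Mean log2 CPM of striatal, excitatory neuron and choroid plexus markers, and summed CPM of 20 liver transcripts on a log axis, for each of the 16 libraries by group; digits are replicate numbers and lines the mean of 4. Striatal markers are highest in Hq-mut 3 (5.68) and Aifm1-KI 2 (5.28), and liver transcripts in Aifm1-WT 2 (496) and Aifm1-WT 1 (422).

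The remaining lists did not pass in Hq-mut. Medians were 0.09 for complex I assembly and import (camera adjusted p = 0.208), 0.02 for mitochondrial chaperones (0.420), 0.07 for antioxidant genes (0.208), 0.04 for p53 targets (0.478). Values were 0.06 for the TCA cycle (0.0829), 0.14 for reactive astrocytes (0.118, with the complement gene C4b at 0.92, SE 0.41), 0.04 for disease-associated microglia (0.639), -0.07 for astrocytes (0.291) and -0.02 for microglia (0.607). Without the pair numbered 2, the last 2 passed as lower, astrocytes at -0.16 (0.0143, adjusted p = 0.848 with an estimated correlation) and microglia at -0.16 (0.00349, adjusted p = 0.835 with an estimated correlation). They were 0.03 for inhibitory neurons (0.666), 0.16 for excitatory neurons (0.191), -0.15 for oligodendrocyte precursors (0.208), 0.01 for endothelium (0.817), 0.03 for meninges (0.420), 0.02 for hippocampus (0.0891) and -0.06 for thalamus (0.633). X-linked neighbours of Aifm1 lay at 0.00042 (0.609), genes that differ between strains at 0.22 (0.159) and sex-linked genes at 0.00017 (0.807). With the block, TCA cycle genes passed (median 0.06, camera adjusted p = 0.0286, adjusted p = 0.609 with an estimated correlation). So did reactive astrocyte genes (0.17, 0.0224, adjusted p = 0.609 with an estimated correlation) and strain genes (0.28, 0.016, adjusted p = 0.609 with an estimated correlation). The test was lower while the median was above 0 for disease-associated microglia, X-linked neighbours, sex-linked genes, inhibitory neurons, endothelium and meninges. Of these only endothelium had a mean above 0, and microglia had a median below 0 with a mean of 0.01. In all, 13 of 33 lists passed and 17 with the block, 0 with an estimated correlation and 0 by fry, and 7 passed without Hq-WT 4. The 17 with the block held all 13, each in the same direction. List fits without a single Hq library keep its partner and do not use the block, so calls lost in them are not a test with pairing.

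**Figure D3:**
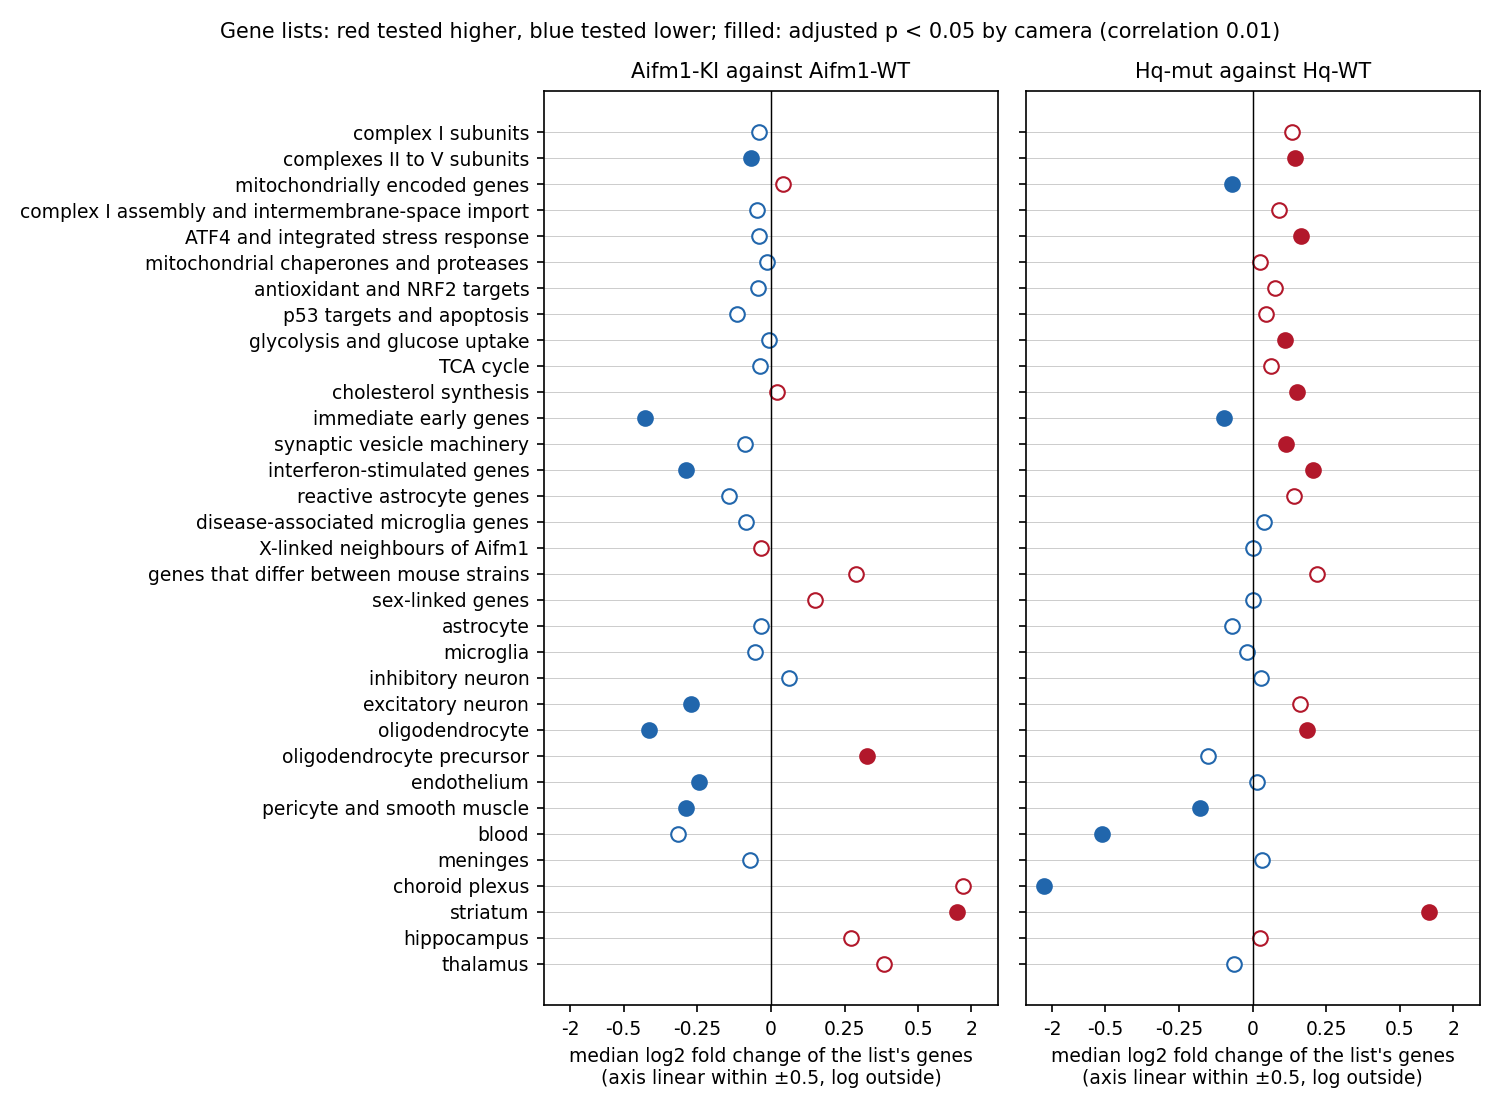
Median log2 fold change of each of the 33 gene lists in Aifm1-KI against Aifm1-WT and Hq-mut against Hq-WT, red where the list tested higher and blue where lower, filled where the camera adjusted p was under 0.05; the axis is linear within 0.5 of 0 and logarithmic outside. Striatal markers are filled and higher in both lines (1.36 and 1.07), while interferon-stimulated genes are filled and lower in Aifm1-KI (-0.29) and higher in Hq-mut (0.21).

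The effects of the mutations were then compared with each other over all 16 libraries. The effect on Aifm1 differed by 2.95 on the log2 scale (SE 0.19, edgeR adjusted p = 5.5e-07), Aifm1-KI minus Hq-mut, and that on Gm6166 by -2.22 (SE 0.31, edgeR adjusted p = 0.0198). Edn1 rose in Hq-mut and was at 0.17 in Aifm1-KI (edgeR adjusted p = 0.809), and its difference of effects was called by DESeq2 (-1.76, adjusted p = 0.000435) and not by edgeR. Of the 33 lists, 15 passed, 3 higher and 12 lower, 0 with an estimated correlation and 0 by fry. With the block 13 passed, all among the 15, 0 with an estimated correlation, and fry called 1, interferon-stimulated genes (adjusted p = 0.0496). The effects on interferon-stimulated genes differed by a median of -0.53 (camera adjusted p = 2.8e-07, adjusted p = 0.143 with an estimated correlation), with 15 of 17 lower. Without Hq-WT 4 the median was -0.68 (2.3e-09, adjusted p = 0.0229 with an estimated correlation), the only fit with libraries left out where a list passed with an estimated correlation. These genes were also higher in Aifm1-WT than in Hq-WT, at a median of 0.38, and the same wild-type libraries enter both comparisons. Levels of the wild types and opposite effects of the mutations thus cannot be told apart for this list. The same limit holds for oligodendrocyte markers, reactive astrocyte genes and mitochondrially encoded genes, at 0.47, 0.38 and -0.22 in Aifm1-WT against Hq-WT. The effects on ATF4 genes differed by -0.22 (camera adjusted p = 7.5e-05, adjusted p = 0.571 with an estimated correlation), and by -0.10 without Hq-mut 2 (0.00739, adjusted p = 0.773 with an estimated correlation). The interferon and ATF4 lists kept their camera call in 21 of 21 fits with libraries left out or with the block. Oligodendrocyte markers differed by -0.57, 10 of 10 lower (camera adjusted p = 6.3e-05, adjusted p = 0.571 with an estimated correlation), but by -0.20 without Aifm1-KI 2 and 4 (0.059) and -0.30 without Hq pair 2 (0.0699). Synaptic vesicle genes (-0.23, 0.000688), excitatory neurons (-0.32, 0.0048) and oligodendrocyte precursors (0.47, 0.0048) also lost their calls without Aifm1-KI 2 and 4, with medians of -0.09 (0.0672), -0.03 (0.382) and 0.10 (0.382). Precursors lost it without Hq-WT 3 as well (0.077). Of the 21 fits, synaptic vesicle genes kept their camera call in 20, excitatory neurons in 19 and precursors in 18. Complexes II to V (-0.22, 0.0048) and I (-0.17, 0.0338) tested lower, yet without Hq-mut 2 they were at 0.13 (0.124) and 0.18 (0.00591, adjusted p = 0.935 with an estimated correlation), and without Hq-WT 3 at -0.19 (0.0838) and -0.12 (0.295). Without Hq pair 2 they were at -0.05 (0.0699) and -0.0039 (0.595). Complexes II to V kept their call in 18 of the 21 fits and complex I in 12. Choroid plexus markers differed by 4.28 (0.00632), by 2.22 with the block (0.0551), by 1.33 without Aifm1-KI 2 (0.244) and by 1.18 without Hq-WT 2 (0.685), while Aifm1-WT 4 had a mean log2 CPM of 2.83 over them. Mitochondrially encoded genes (0.19, 0.0338) did not pass with the block (0.17, 0.0692). These and complex I, endothelium, reactive astrocyte, immediate early, TCA cycle and glycolysis genes each did not keep their call without 6 to 9 of the 16 libraries, left out singly. The lowest adjusted p with an estimated correlation was 0.571 over the 14 lists besides interferon-stimulated genes. The edgeR test called 2 of 19129 genes, with 972 at an unadjusted p under 0.05. The call of Gm6166 was lost without Aifm1-KI 1 (edgeR adjusted p = 0.0696), 2 (0.0511), 3 (0.0582) or 4 (0.0612), Aifm1-WT 1 (0.0807), 2 (0.0524) or 4 (0.0722), Hq-mut 1 (0.0509), or Hq-WT 1 (0.0617), 2 (0.0684), 3 (0.0716) or 4 (0.0663), and without Aifm1-KI 2 and 4 together (0.168) or Hq pair 2 (0.157).

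Across 17693 genes tested in both lines, the differences of mean log2 CPM in Aifm1-KI and Hq-mut had a Pearson r of 0.003 and a Spearman rho of -0.053, across genes, which are not independent replicates. Without Aifm1-KI 2 and 4 and Hq-mut 3 these were 0.07 and 0.009. Of the 35 splits of the Hq line, 34 gave an r as large in size (permutation p = 0.971). In both lines together 0 genes were called by edgeR, since it called 0 in Aifm1-KI, where DESeq2 called 82 and 2094 had an unadjusted p under 0.05.

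The wild types of the lines were compared as the background of both mutants. In Aifm1-WT against Hq-WT, 101 of 18106 genes were called by edgeR, 60 higher and 41 lower. The genes named here were chosen after their values were seen. Ints7, an Integrator complex subunit on GRCm38 chromosome 1, was at 54.3 ± 1.88 CPM against 27.3 ± 1.49 CPM (edgeR adjusted p = 0.000157). Slc5a5, the sodium-iodide transporter on chromosome 8, was at 24.3 ± 0.83 against 5.81 ± 2.39 CPM (log2 fold change 2.06, edgeR adjusted p = 0.0010). The Wnt antagonist genes Sfrp1 (-1.29, 0.0010) and Frzb (-1.16, 0.00743) were lower. Alb, the serum albumin gene made in liver, was higher (6.18, 0.0256), at 89.7 ± 85.4 CPM in Aifm1-WT, and lost its call without Aifm1-WT 1 (0.071), Aifm1-WT 2 (0.0665) or Hq-WT 1 (0.103). Of the 33 lists, 15 passed, 8 higher and 7 lower, 0 with an estimated correlation (lowest adjusted p = 0.426) and 0 by fry. Meningeal genes were higher, 8 of 8, with a median of 1.13 (camera adjusted p = 3.1e-05, adjusted p = 0.429 with an estimated correlation). Interferon-stimulated genes, which tested lower in Aifm1-KI and higher in Hq-mut, were higher in Aifm1-WT, 16 of 17, at 0.38 (camera adjusted p = 0.000381, adjusted p = 0.587 with an estimated correlation). Also higher were reactive astrocyte genes (0.38, 0.000105, adjusted p = 0.426 with an estimated correlation), oligodendrocyte markers, 10 of 10 (0.47, 0.00137, adjusted p = 0.638 with an estimated correlation), and markers of microglia, pericytes and hippocampus. Thalamus markers passed too, with 3 higher and 3 lower (0.26, 0.0053, adjusted p = 0.426 with an estimated correlation), and were at 0.13 without Aifm1-WT 4 (0.018, adjusted p = 0.349 with an estimated correlation). Subunits of complexes II to V were lower, 36 of 39, at -0.19 (camera adjusted p = 2.1e-05, adjusted p = 0.638 with an estimated correlation), as were those of complex I, 34 of 36, at -0.20 (0.000105, adjusted p = 0.645 with an estimated correlation). Mitochondrially encoded genes were lower, 7 of the 7 that passed the filter on low counts, at -0.22 (camera adjusted p = 0.000381, adjusted p = 0.638 with an estimated correlation). Complex I assembly, mitochondrial chaperones, the TCA cycle and inhibitory neurons were lower too. Without Hq-WT 2, 8 lists passed, 5 of them among the 15, with medians of -0.05 for complexes II to V (0.202), -0.01 for complex I (0.603) and 0.27 for oligodendrocytes (0.0966). Interferon-stimulated genes were then at 0.18 (0.00441, adjusted p = 0.765 with an estimated correlation). The 7 lists named without values lost their call without Hq-WT 2 (0.0708 to 0.603). Of the 8 libraries left out singly, hippocampus lost its call without 5, inhibitory neurons without 4, chaperones, TCA cycle, microglia and pericytes without 3 each, and complex I assembly without 1. The count was 37 without Aifm1-WT 1, 32 without Aifm1-WT 2, 42 without Aifm1-WT 3, 49 without Hq-WT 1, 169 without Hq-WT 2, 231 without Hq-WT 3 and 174 without Hq-WT 4, and DESeq2 called 421. The share of counts from CT010467.1, a ribosomal RNA gene, was 0.0417 to 0.0669% in Aifm1-WT and 0.225 to 0.895% in Hq-WT, without overlap, so the libraries also differed in make-up. Line, stock, this share and any batch that follows the line cannot be told apart in this comparison.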

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

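The tests of striatal, liver and Gm6166 patterns, and the splits of libraries, were chosen only after the results were seen. Single libraries far from the other 3 of their group were found in 27 of 217 sets of 4 tested, where 10.8 are expected for independent, normally distributed values. Some of these sets are genes or marker levels chosen after their values were seen, and the sets share the same 16 libraries. The excess over 10.8 therefore decides nothing.

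Striatal markers were high in Aifm1-KI 2, Aifm1-KI 4 and Hq-mut 3, which were picked for these levels. In Hq-mut 3, Drd2 was at 20 CPM (others 1.99 to 4.75), Adora2a at 21.9 (1.99 to 3.21) and Penk at 139 (28.5 to 43.2), and the Hq-WT 3 striatal level was low, at 2.99 (3.27 to 3.30). Tissue from the neighbouring striatum and a genotype effect cannot be told apart, because the 3 high libraries are all mutant and 6 of 8 mutant libraries were above every wild type of their line. The gains of the 10 markers correlated across genes between these libraries at r = 0.714 to 0.945, which does not decide, since the libraries were picked by these markers and gains in CPM follow how abundant a gene is under any common rise. Penk gained 179 CPM in Aifm1-KI 2, and 9 of the 10 markers have a mean of at least 1 CPM in the 8 wild types, with 0 in another list.

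Transcripts made in liver were high in Aifm1-WT 1 and 2. Alb was at 155, 171, 18.3 and 13.8 CPM in Aifm1-WT 1 to 4. It was at 7.88 or less elsewhere and lowest in its group in Aifm1-KI 4, at 1.40 (6.78 to 7.88), and Mup3 and Serpina3k were at 48.2 and 41.3 CPM in Aifm1-WT 2. Liver RNA or reads may be the source, since the 20 genes kept their ratios between Aifm1-WT 1 and 2 (SD of the log2 ratio 0.156), but between 1 and 3 the SD was 0.58, above the limit set for a common factor. The Hq-WT libraries, also wild type, summed to 4.86 to 13.8 CPM, which argues against a high level as a trait of wild-type Aifm1 as such. They come from another line, so an effect within the Aifm1 line cannot be told apart. There the wild types differed by 12.8-fold among themselves and by 12.4-fold from Aifm1-KI on average, and 4 of 4 lay above all Aifm1-KI. Of the 20 genes, 1 has a mean of at least 1 CPM in the 8 Hq libraries, and 0 are in another list.

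The effects of the mutations differed by test for Aifm1 (2.95 on the log2 scale) and Gm6166 (-2.22), and Gm6166 was low in Hq-WT 3, at 1.29 CPM (1.59 to 1.63). Reads of Fabp5 at a fixed share are argued against for Gm6166, since the log2 fold changes of the pair differed by 2.39 (SE 0.343). A sequence variant that moves Fabp5 reads to Gm6166 may be the source and cannot be told apart, because Fabp5 lost 1.45 CPM against 5.58 gained, a gap of 1.97 SE with the Hq libraries paired (SE 2.10, from 0.408 to 10.2 CPM by pair) and 1.55 SE unpaired, short of the limit of 2. With the paired SE of the Fabp5 loss alone (1.59) the gap is 2.59 SE, but that leaves out the spread of Gm6166. The loss from Fabp5 is also no firm test of a variant. Where only uniquely placed reads are counted, reads that match both genes count for neither, and Gm6166 could gain them without a loss from Fabp5. Other transcripts resemble Gm6166 too, such as the pseudogene Gm14328 (96.6% identical over 409 bases), and their counts were not checked. A change in transcription of the locus was not tested.

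Choroid plexus genes stood apart in single libraries. Ttr was at 2650 CPM in Aifm1-KI 2 (17.4 to 36), 323 in Aifm1-WT 4 (23.5 to 40.9) and 5350 in Hq-WT 2 (6.31 to 98.1), and Sostdc1 at 14.1 in Aifm1-KI 2 (0.845 to 1.66) and 2.54 in Aifm1-WT 4 (0.601 to 0.665). Cldn2 was at 12 CPM in Hq-WT 2 (0 to 1.11), and the choroid plexus level at 4.94 in Aifm1-KI 2. Hq-mut 2 stood apart in Dnaja3 at 79.1 CPM (62.4 to 64.5), Kdm5d at 23.8 (36.1 to 36.6), Uty at 17.5 (25.5 to 26.7) and summed liver transcripts at 9.06 (4.59 to 5.14). Other single libraries were Apaf1 in Aifm1-WT 2 at 16.4 CPM (13.1 to 13.4), Aifm1 in Hq-WT 2 at 25.8 (23.1 to 23.5) and Aif1 in Hq-WT 4 at 4.37 (6.69 to 7.14). Further ones were Slco1a4 in Hq-WT 3 at 46.1 (35.6 to 37.3), Ramp3 in Hq-WT 2 at 13.0 (8.41 to 8.98) and Ddx3y in Aifm1-KI 2 at 78.8 (70 to 71.2). Sycp1 was at 0.0475 CPM in Aifm1-WT 1 and 0 in the other 3. Slc5a5 was high in Hq-WT 2 at 9.35 (4.32 to 5.11), as was Frzb in Aifm1-WT 1 at 14.1 (9.44 to 9.97), and the share of the ribosomal RNA gene CT010467.1 in Aifm1-KI 4 at 0.381% (0.0512 to 0.0819).

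Other splits of the libraries were tested for each count of called genes. For the edgeR count of 0 in Aifm1-KI they decide nothing, as any split gives at least 0 (35 of 35, highest other 1). Chance cannot be excluded for its DESeq2 count of 82, as 3 of 35 splits gave as many (highest other 374). It cannot be excluded for Hq-mut, where 2 of 35 splits gave at least 3. The other one, of libraries 1 and 2 against 3 and 4, gave 169, which points to a structure of the replicate numbers. The 7 other splits that part all 4 pairs gave 0. With the block, the 8 splits are too few for a share under 0.05 (real 3, highest other 1, with 1 split as large). For the difference of effects, 7 of 100 splits that ignore the Hq pairs gave at least 2 (highest other 21), so chance cannot be excluded by them. Of 100 splits that exchange Hq genotypes only within pairs, 9 did (highest other 3). These decide nothing, since the pairs have only 8 swaps, and the 9 are those with the Hq genotypes as labelled, while the 91 others gave 0. For the wild types, 1 of 35 splits gave 101 or more (highest other 1), a share under 0.05 and the smallest that 35 splits can give. This argues against chance but does not exclude it, as the test is coarse and was chosen after the results were seen.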

How the results depend on the processing

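The tests chosen only after the results were seen are edgeR's likelihood ratio test, the fits without Aifm1-KI 2 and 4, without Aifm1-WT 1 and 2 and without a pair of Hq libraries, the striatal marker covariate, and the other tools with the block in the Hq line. Aifm1 kept its call in Hq-mut in 22 of 22 alternatives, with adjusted p-values of 2.6e-51 to 0.0458. Edn1 kept it in 15 of 22, with adjusted p-values up to 0.406, and Gm6166 in 12 of 22, up to 0.662. For the difference of effects, Gm6166 kept its call in 13 of 28, up to 0.256. In Aifm1-KI, DESeq2 and the likelihood ratio test each called Slc16a1, Tdo2 and Alb, which edgeR did not. Genes not called by the main test in Hq-mut but called in some alternatives were Trib3 (2 of 20), Apln (2 of 22) and Hba-a2 (1 of 22). Where a value changed, the cause was not tested, except that fits with fewer libraries or with a filter hold fewer values by construction. The lowest depth, 10671580 counts in Hq-WT 3, allows up to 0.281 CPM at a count of 0, so genes below that level were not measurable there.

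Counts of called genes moved with the tool. In the simulations DESeq2 made more false calls than edgeR in every comparison. DESeq2 called 82 in Aifm1-KI, 5 for the difference of effects and 421 between the wild types, the likelihood ratio test 110, 7 and 427, and limma-voom 1 for the difference of effects, as did the fits without Aifm1-KI 2 and 4 and without Hq pair 2. Between the wild types, upper-quartile factors gave 64, no filter 560, and the fit without Aifm1-WT 1 and 2 gave 20, of which 19 were among the 101. In the Hq line, the fits without pair 2 and without pair 3 each called 1, Aifm1, while DESeq2 with the block called 33 and the likelihood ratio test with the block 54. With a library left out, the counts ran from 0 to 46 in Aifm1-KI (46 without Aifm1-KI 3), 1 to 2 in Hq-mut, 1 to 2 for the difference of effects and 32 to 231 between the wild types.

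For some lists the test changed direction. Their medians were as follows. X-linked neighbours in Aifm1-KI were at -0.043 with upper-quartile factors and -0.0474 without a filter, thalamus in Hq-mut at 0.0131 without a filter, and hippocampus at -0.0027 in Aifm1-KI and -0.0342 in Hq-mut with the CPM filter. With all 16 libraries in 1 fit, inhibitory neurons in Aifm1-KI were at 0.0565 and endothelium in Hq-mut at 0.0143.

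The replicate block was also fitted in the Aifm1 line, where the numbers share no more than a name: same-numbered libraries correlated across genes at -0.02 to 0.082, and 4 of 8 correlated best with their own number. Between the wild types the range was -0.081 to 0.113, with 1 of 8. With the block, 0 genes were called in Aifm1-KI (1995 at an unadjusted p under 0.05) and 99 between the wild types, and strain genes passed in Aifm1-KI (camera adjusted p = 0.0176, adjusted p = 0.701 with an estimated correlation). Ttr changed sign, at -0.0077, and the test changed direction for X-linked neighbours (median -0.0346) and hippocampus (0.2214). Between the wild types, immediate early genes passed as lower (-0.13, camera adjusted p = 0.00489, adjusted p = 0.680 with an estimated correlation). In the Hq line the block changed no call of a named gene and no other list than those given with it.

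Without Aifm1-KI 2 and 4, 14 lists passed in Aifm1-KI, 4 of them among the 9 and 0 with an estimated correlation (lowest adjusted p = 0.0858), while fry called 2, astrocytes and disease-associated microglia. Besides the 4 glial lists, those gained were mitochondrially encoded genes (camera adjusted p = 0.00252), antioxidant genes (-0.05, 0.0459), inhibitory neurons (-0.07, 0.00766), blood (-0.54, 0.000376), meninges (-0.71, 2.0e-08) and choroid plexus (0.0128), all lower. Genes that changed sign were mt-Nd6 -0.0438, Sostdc1 -0.2653, Lhx9 -0.0757, Edn1 -0.02 and Ttr -1.8981. Lists whose test changed direction had medians of mitochondrially encoded genes -0.1027, TCA cycle -0.0135, synaptic vesicle 0.0103, excitatory neuron 0.0502, oligodendrocyte precursor 0.0135, choroid plexus -1.1956 and hippocampus -0.0038. With the striatal marker level as a covariate, 10 lists passed, 3 of them among the 9 and 0 with an estimated correlation (lowest adjusted p = 0.143). Lost were complexes II to V, endothelium, immediate early genes (camera adjusted p = 0.325), excitatory neurons (0.416), oligodendrocytes (0.0865) and striatum (0.963), the last since it is the covariate. Gained were reactive astrocytes (-0.41, camera adjusted p = 1.3e-07), disease-associated microglia (-0.33, 1.5e-10), astrocytes (-0.19, 4.3e-07), microglia (-0.27, 7.8e-09), meninges (-1.23, 2.1e-14), mitochondrially encoded genes (0.0188) and choroid plexus (6.8e-07), all lower, and precursors passed as lower (0.00909). Genes that changed sign were mt-Nd6 -0.0689, Yme1l1 -0.0299, Gsta4 -0.0228, Apaf1 -0.0668, Idh3g 0.0101, Syn2 -0.0436, Opalin 0.102, Cspg4 -0.131, Dcn -0.2715, Sostdc1 -1.6778, Lhx9 -0.978, Penk -0.4114 and Ttr -2.6387. List medians, where the test changed direction, were mitochondrially encoded genes -0.1347, TCA cycle 0.014, immediate early genes 4e-04, synaptic vesicle 0.0924, X-linked neighbours -0.0225, excitatory neuron -0.0025, oligodendrocyte 0.1399, oligodendrocyte precursor -0.1796, choroid plexus -3.1149, hippocampus -0.1896 and thalamus -0.1873.

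For the difference of effects, 11 lists passed without Aifm1-KI 2 and 4, 8 without Hq pair 2 and 13 without Hq pair 3, with 5, 7 and 12 among the 15 and 0 with an estimated correlation (lowest adjusted p = 0.152, 0.761 and 0.396). Gained were antioxidant, cholesterol synthesis, disease-associated microglia, microglia, meninges and hippocampus lists, all lower, in the first, blood, higher, in the second, and striatum in the third. Striatal markers, at 0.36 with 6 of 10 higher over all libraries (camera adjusted p = 0.132), were then at 1.23, 10 of 10 higher (2.0e-08, adjusted p = 0.430 with an estimated correlation). They also passed without Hq-mut 3 (1.13, 1.7e-06, adjusted p = 0.453 with an estimated correlation) and without Aifm1-KI 3 (0.51, 0.0123, adjusted p = 0.744 with an estimated correlation), but not without Aifm1-KI 2 and 4. Besides the fry calls given, fry called 1 list in each of 4 fits: in Aifm1-KI with the CPM filter and without Aifm1-WT 4, and for the difference of effects without Hq-mut 1 and without Hq-WT 4. It called 2 between the wild types without Hq-WT 3.

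Without Hq pair 2, 8 lists passed in Hq-mut, 6 of them among the 13. Astrocytes (-0.16, camera adjusted p = 0.0143) and microglia (-0.16, 0.00349) were gained, both lower (adjusted p = 0.848 and 0.835 with an estimated correlation). Genes that changed sign were Opalin -0.1166, Eif2s3y -0.0519, Uty 0.0601 and Ttr 0.0417. List medians, where the test changed direction, were complex I -0.0401, complexes II to V -0.0389, complex I assembly -0.0022, p53 targets 0.0551, sex-linked genes 0.0041, inhibitory neuron 0.0335, oligodendrocyte -0.087, choroid plexus 0.0417 and thalamus -0.0724. Without pair 3, complex I subunits were gained (0.18, camera adjusted p = 0.0263, adjusted p = 0.823 with an estimated correlation), and list medians, where the test changed direction, were sex-linked genes -0.0351, microglia 0.0365 and endothelium -0.0216.

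With single libraries left out, the median moved by over 1.5-fold or turned at least once for 6 of the 9 lists called in Aifm1-KI, 12 of 13 in Hq-mut, 12 of 15 for the difference of effects and 12 of 15 between the wild types. In Aifm1-KI it did not for interferon-stimulated genes, pericytes and striatum, and in Hq-mut not for cholesterol synthesis. For oligodendrocytes, the medians ran from -0.0116 to 0.6405 in Hq-mut and from 0.2719 to 0.8844 between the wild types.

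With each library left out in turn, genes that changed sign, and the medians of lists whose test changed direction, at least once in Aifm1-KI ranged as follows: X-linked neighbours of Aifm1 -0.0737 to -0.0121, inhibitory neuron -0.0067 to 0.083, Ttr -2.1004 to 4.3922, choroid plexus -1.3347 to 2.6748, hippocampus -0.0491 to 0.4375, Gm6166 -0.1034 to 0.0333, meninges -0.2753 to 0.1439, mitochondrially encoded genes -0.0329 to 0.085 and mitochondrial chaperones and proteases -0.0355 to 0.003. In Hq-mut the ranges were disease-associated microglia genes -0.0916 to 0.1445, astrocyte -0.1918 to 0.0726, inhibitory neuron -0.0344 to 0.1048, endothelium -0.0672 to 0.1071, meninges -0.3145 to 0.2881, Uty -0.0903 to 0.1015, complex I subunits -0.2432 to 0.3411, complexes II to V subunits -0.1892 to 0.3251, complex I assembly and intermembrane-space import -0.1026 to 0.2156, mitochondrial chaperones and proteases -0.0174 to 0.1423, antioxidant and NRF2 targets -0.0662 to 0.1474, p53 targets and apoptosis -0.0183 to 0.1257, sex-linked genes -0.0618 to 0.0917, Ddx3y -0.0147 to 0.098, microglia -0.152 to 0.0646, Cldn2 -3.8891 to 0.0751, Eif2s3y -0.0951 to 0.2896, Ttr -5.1765 to 1.7067, choroid plexus -3.0887 to 0.446 and oligodendrocyte precursor -0.2363 to -0.0286. Of the other values for lists in both mutant lines, over the alternatives run, 951 kept direction and call, 92 gained a call and 96 lost it. For named genes in all comparisons these numbers were 1958, 17 and 39. Items called in neither fit count as kept, so these numbers do not show how stable the calls were.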

Other observations

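The tests of gene positions, and the genes named here, were chosen only after the results were seen. In the Hq line, DESeq2 with the block called 33 genes (14 higher, 19 lower), which edgeR with the block did not call beyond Aifm1, Edn1 and Gm6166. Cd93, an endothelial receptor, was at a log2 fold change of 0.95 (DESeq2 adjusted p = 0.000193), Angpt2, an angiopoietin, at 1.48 (0.0458), Ly6a at 1.76 (0.000115) and Apln, the apelin gene that neighbours Aifm1 on the X chromosome, at -0.54 (0.0422). The growth factor-binding protein gene Igfbp2 was lower (-1.20, 9.9e-07), and Scn4b, a sodium channel subunit (0.91, 2.6e-07), the serotonin receptor gene Htr2a (0.58, 0.0138) and Tac1, the substance P precursor (0.80, 0.0498), were higher. This fit keeps Hq-mut 3, whose striatal marker level was high (5.68). Whether Scn4b, Htr2a and Tac1 follow that level was not tested, so their rise may not be an effect of the mutation. Of the 10 listed striatal markers 0 were among the 33, but as a list they rose with the block (median 0.77). The edgeR adjusted p with the block was 0.271 for Cd93 and 0.22 for Angpt2, so these calls depend on the tool. Endothelial markers as a list did not pass with the block, 5 of 10 higher (camera adjusted p = 0.772).

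Genes called between the wild types lay near each other. Of the 101, 35 had another within 1 Mb, against a median of 13 and at most 30 in 1000 random draws (permutation p = 0.000999, the smallest these draws can give), and chromosome 1 held 17 where 6.42 were expected and chromosome 8 held 13 where 5.25 were expected. On chromosome 1, Catspere1 and Catspere2 were both lower in Aifm1-WT (edgeR adjusted p = 0.000107 and 0.000189) and Ints7 and Tatdn3 both higher (0.000157 and 0.00181). A candidate explanation is linked sequence differences between the stocks, as a hypothesis found and tested on the same data, and line and any batch cannot be told apart. Myh7 lost its call without Aifm1-WT 1 and 2 (adjusted p = 0.227).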
